A study of Arabidopsis thaliana with 12 samples.

How the data were processed

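Total RNA of 10-day-old Arabidopsis thaliana Columbia seedlings, grown at 22 °C, was measured on 12 one-colour Affymetrix-type arrays with 3' labelling, per the labels' protocols. The seedlings were wild type or ire1a ire1b double mutants, which lack both of the plant's IRE1 sensors of the endoplasmic reticulum (ER). All received actinomycin D at 75 µM, an inhibitor of transcription, and 2 h later either tunicamycin at 5 mg per litre or its solvent (mock) for 5 h. Tunicamycin blocks N-glycosylation and so causes misfolded protein to build up in the ER. The labels give 4 groups of 3 arrays, numbered 1 to 3 within each group. No label says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

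The deposited values are linear array intensity per probe set (called signal here), made with MAS5 per the submitters' processing notes; the version and its settings are not given in the sources used here. All values are above 0, and the mean without the highest and lowest 2% of probe sets is about 500.1 on each array, so the authors' values carry a common scaling of every array. Such scaling sets all changes relative to the bulk of the array: a fall of most transcripts by the same factor would not be seen. MAS5 values of dim probe sets also vary more than those of bright ones.

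The table held 22810 probe sets, of which 64 are array controls. Of the other 22746, the platform's gene table paired 13513 with 1 gene, 503 with several and 8730 with none listed; 13436 of the single-gene probe sets matched a gene of the RefSeq table (assembly TAIR10.1), which gave current symbols and locus names. Probe sets with several genes or none were tested but not given a gene name. Many genes of interest therefore have no named probe set here, among them IRE1A, IRE1B and the ER chaperone genes BIP1, BIP2 and BIP3. No genome was used, so no positions are given.

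Signals were taken as log2 without further normalization. Probe sets whose mean log2 signal over the 12 arrays lay above the 40th percentile (log2 6.10, a signal of 68.7) were tested, 13647 in all. They held 7355 probe sets of 1 named gene, 286 of several and 6006 with none listed. A linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3), with eBayes and an intensity trend in the prior variance, so that the 4 groups share 1 estimate of the spread. It gave 5 comparisons: tunicamycin against mock in wild type, the same in ire1a ire1b, the interaction (the wild-type effect minus the ire1a ire1b effect), and ire1a ire1b against wild type under mock and under tunicamycin. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A transcript was counted as lower in an IRE1-dependent way when it passed downward both in wild type and in the interaction. Values are log2 changes ± standard error (SE) of the model with 3 arrays per group, or mean signal ± SD.

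Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the brightest) and 5 or more tested members. There were 44 such tests, adjusted together, and each was repeated with an estimated correlation and with fry. The 21 lists were ER stress genes (UPR), heat shock, peroxidases, arabinogalactan proteins, xyloglucan transglucosylases (XTH) and expansins, lipid transfer proteins, secreted defence proteins, vacuolar and ER body proteins, other cell wall proteins, aquaporins, ribosome, proteasome, photosynthesis, short-lived transcripts, clock, root markers, cell death, reference genes, the secretory cargo lists joined, and the plastid-encoded and mitochondria-encoded genes. Arabinogalactan, aquaporin, root marker and mitochondria-encoded genes had no tested member. The planned share of proteins with a hydrophobic N terminus needs protein sequences, which were not used here. The plan allowed a search of gene titles for words of secreted proteins in its place. This search was made on the synonyms of the RefSeq table, and a gene whose synonyms held a space was counted as having a title. Medians of gene sets carry 95% bootstrap intervals from 2000 draws, which resample genes or transcripts and not arrays.

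Genes are named by a rule: per comparison, the probe sets of 1 named gene past the threshold whose groups did not overlap in any array, up to 12 largest rises and 12 largest falls, or the smallest unadjusted p where fewer than 5 passed. Up to 4 members per list with the smallest p in wild type, and BZIP60, BZIP28, IRE1A, IRE1B and the BIP genes, were added. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined, except where stated otherwise. The rule does not cover ARA12, AT4G01610, BETA-VPE, AT3G01190, the secreted defence genes under mock, the probe sets with no gene listed and the interaction values of genes named in wild type; these were chosen after their values were seen.

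The fit was tested on simulated data with the spread of these arrays and 50 changed probe sets per size among 13647. For the wild-type effect, 68% of log2 changes of 1 and 100% of those of 2 were called, with 10 false calls; for the interaction, 44% and 96% were called, with 7 false calls. The arrays correlated at r between 0.938 and 0.961 over all probe sets and no pair was a duplicate. The number of arrays limits the precision. The median SD of log2 signal per probe set was 0.16 in wild-type mock, 0.15 in wild-type tunicamycin, 0.19 in ire1a ire1b mock and 0.21 in ire1a ire1b tunicamycin arrays.

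The replicate numbers are shared by the groups, so it was checked whether same-numbered arrays deviated together from their group means. The criterion for pairing was a correlation above 0.1 in every pair. In ire1a ire1b the mock and tunicamycin arrays of numbers 1, 2 and 3 met it, with correlations of 0.11, 0.44 and 0.51, although mock array 2 and tunicamycin array 1 also had 0.16; there the fit with replicate as a block is given beside the result. In wild type (0.13, 0.02 and 0.12) and between genotypes they did not all exceed 0.1. The block is 1 effect per replicate number over all 12 arrays. It is thus shared with wild type and does not pair the mutant's arrays alone. The alternatives were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, a pseudocount (23.8, the 20th percentile of signal), eBayes without a trend, the replicate block, array weights, only the 6 arrays compared, and each of the 12 arrays left out.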

Results

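The series asks which transcripts disappear during ER stress through IRE1, an ER membrane protein with an RNase domain, when new transcription is blocked. It holds 12 arrays of whole seedlings in 4 groups of 3: wild type and ire1a ire1b, each with mock or tunicamycin, all in the presence of actinomycin D. The 2% trimmed mean signal was about 500.1 on every array, and the median signal lay between 106.7 on ire1a ire1b mock array 3 and 118.8 on wild-type mock array 1. The 3' over 5' signal ratio of the control transcripts, a measure of RNA integrity, was 1.27 ± 0.03 in wild-type mock and 1.34 ± 0.14 in wild-type tunicamycin arrays (log2, SD, n = 3), and the difference of 0.08 had an exact permutation p of 0.5, two-sided. The hybridization controls were higher by 0.07 in wild-type tunicamycin arrays (exact permutation p = 0.1) and the poly-A controls by 0.21 (exact permutation p = 0.3). An exact test of 3 arrays against 3 cannot go below 0.1. IRE1A and IRE1B have no named probe set here, so the loss of both transcripts in the mutant was not checked.

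The comparison of tunicamycin with mock in wild type shows which transcripts fell or rose under ER stress with transcription blocked. PYK10, the abundant beta-glucosidase of ER bodies, went from a signal of 22998 ± 928 to 10067 ± 379 (SD, n = 3), a log2 change of -1.19 ± 0.07 with an adjusted p of 3.72e-07. GAMMA-VPE, a vacuolar processing protease, fell 6.18-fold from 2549 ± 562 to 406.6 ± 36.9, and ATPMEPCRB, a pectin methylesterase of the cell wall, fell 5.99-fold from 540.8 ± 109 to 89.2 ± 5.86. AT1G33600, a leucine-rich repeat protein gene, had -3.49 ± 0.60, but its signal under tunicamycin (67.2 ± 36.8) lay below the filter value of 68.7, so the size of its fall is uncertain. In all, 788 of 13647 probe sets fell and 59 rose in limma's test after Benjamini-Hochberg adjustment, of which 288 and 16 by 2-fold or more. Of these, 374 falls and 33 rises were probe sets of 1 named gene. The count of rises was 35 without wild-type tunicamycin array 2, 36 without wild-type tunicamycin array 1 or mock array 3, 89 with replicate as a block, 110 with only the wild-type arrays and 169 with array weights.

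Further falls among the named genes were AT4G29270, an acid phosphatase family member, at -2.41 ± 0.14, and the class III peroxidase AT5G19890 at -2.32 ± 0.36. ChiC, a class V chitinase, changed by -2.32 ± 0.29 and the peroxidase gene AT4G30170 by -2.29 ± 0.20. AT1G21670 changed by -2.21 ± 0.37, the osmotin gene OSM34 by -2.17 ± 0.20, the papain-type protease gene AT4G16190 by -2.05 ± 0.27 and AT1G21680 by -2.00 ± 0.32. AT3G56060, a flavoprotein oxidoreductase gene, had -2.46 ± 0.36, of uncertain size because its signal under tunicamycin (48.2 ± 8.67) lay below the filter value. The largest falls among probe sets with no gene listed were 10.0-fold and 8.21-fold. Few falls were called among dim probe sets: when the tested probe sets were ranked by wild-type mock signal, 0.37% of the dimmest 20% and 10.1% of the brightest 20% fell. The mock arrays used for the ranking also enter the change, and dim values vary more. The contrast therefore need not be a property of the transcripts.

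The secretory cargo lists, fixed in advance, carried this fall as groups. Of their 72 tested members, 30 fell and 0 rose (1 rose at an unadjusted p below 0.05), with 41 falls and 1 rise adjusted over the list alone; the median log2 change was -0.61 (camera adjusted p = 9.96e-33, and 0.00078 with an estimated correlation). Among 35 peroxidases 15 fell, with a median of -0.63, including the abundant PRXR1 (from 18927 to 8951), AT5G64100 at -0.83 ± 0.12 and AT1G71695 at -0.63 ± 0.10; 22 fell adjusted over the list alone, and the adjusted p was 0.0016 with an estimated correlation. Among 7 vacuolar and ER body genes 6 fell, with a median of -1.19: PYK10, GAMMA-VPE, NAI2 (a protein needed for ER body formation, -1.46 ± 0.10), the subtilase gene ARA12 (-1.23 ± 0.12), and the cathepsin B-like protease genes AT1G02305 (-1.13 ± 0.10) and AT4G01610 (-0.99 ± 0.15). Adjusted over the list alone 7 fell, the other being BETA-VPE at -0.46 ± 0.19 (adjusted p = 0.26 over all probe sets), and the adjusted p was 0.0092 with an estimated correlation.

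Among 15 XTH and expansin genes, which remodel cell walls, 4 fell: EXGT-A3 (-0.88 ± 0.12), XTH32 (-0.81 ± 0.13), XTH19 (-0.87 ± 0.20) and EXLA1 (-0.76 ± 0.19); adjusted over the list alone 5 fell and 1 rose, and the adjusted p was 0.0092 with an estimated correlation. Of 8 secreted defence genes 2 fell, OSM34 and the defensin gene LCR69 (-0.46 ± 0.12), with 3 falls adjusted over the list alone and an adjusted p of 0.017 with an estimated correlation. Both tested members of the other cell wall list fell, ATPMEPCRB and COB (-0.88 ± 0.11), a protein that guides cellulose deposition, and both fell adjusted over the list alone. Of 5 lipid transfer genes 1 fell, the very bright AT2G45180 (-0.54 ± 0.10), with 2 falls adjusted over the list alone; the list's call was lost with an estimated correlation (adjusted p = 0.23) and without wild-type mock array 1 (adjusted p = 0.053). The calls of XTH19, EXLA1 and LCR69 ended when 1 wild-type array was left out, with adjusted p values of up to 0.061 (without tunicamycin array 1), 0.14 (without mock array 2) and 0.19 (without mock array 3). That of LCR69 also ended with each array centred on its median (0.091).

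No fall passed in the lists of genes whose products do not enter the ER. These nuclear lists are small, and over all tested probe sets 788 of 13647 fell, so few falls would be counted in them in any case. None of 11 ribosomal protein genes (median +0.16), 2 proteasome genes (+0.11), 6 photosynthesis genes (+0.03) or 5 reference genes (+0.07) passed in limma, and at an unadjusted p below 0.05 there were 0 falls in these lists and 1 rise, in the reference list. Adjusted over each list alone, 0 passed in any of them. Of 66 plastid-encoded genes 1 rose, petG (+0.73 ± 0.20; the call ended without wild-type tunicamycin array 1, adjusted p = 0.21), and 0 adjusted over the list alone; their camera adjusted p was 0.064. The median of all tested probe sets was +0.09. Both tested heat shock genes, ATHSP22.0 and AT1G53540, stayed short of the threshold, as did both short-lived transcripts, WRKY53 (+0.52 ± 0.18, past it adjusted over the list alone) and STZ, and the clock gene GI (+0.01 ± 0.17). Adjusted over the list alone, 0 heat shock genes and 0 clock genes passed. Both tested members of the cell death list fell, scpl48 (-0.58 ± 0.14) and AT4G04460 (-0.90 ± 0.24), which encode a serine carboxypeptidase-like and an aspartyl protease, and both fell adjusted over the list alone. Their calls ended without wild-type mock array 2 (adjusted p = 0.13 and 0.16).

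The rises in wild type included ER stress genes despite the actinomycin D. Of 7 tested UPR genes 3 rose: DER1, of ER-associated degradation, by +0.86 ± 0.15, the calnexin gene AT5G07340 by +0.71 ± 0.14, and BZIP60, whose mRNA IRE1 is known to splice, by +0.67 ± 0.17, from 839.6 ± 133 to 1342 ± 265. The same 3 rose adjusted over the list alone. The list's median was only +0.01 against a mean of +0.29. Its camera adjusted p was 0.13, against 0.50 with an estimated correlation and 0.042 with fry. BZIP28 changed by -0.04 ± 0.19 (adjusted p = 0.94). The BZIP60 call had an adjusted p of 0.035 and ended in 5 of the 12 fits without 1 array, at most 0.16 without wild-type tunicamycin array 3. Other named rises were AT4G34630 (+1.97 ± 0.18), AT1G29060 (+1.35 ± 0.22) and AT4G29520 (+1.28 ± 0.19). AT3G55700, a glucosyltransferase family gene (+1.98 ± 0.24), and AT1G64460 (+1.83 ± 0.38) also rose, from mock signals of 60.6 and 59.8 below the filter value, so the size of these rises is uncertain. The largest rises among probe sets with no gene listed were 17.9-fold and 11.3-fold.

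**Figure D1:**
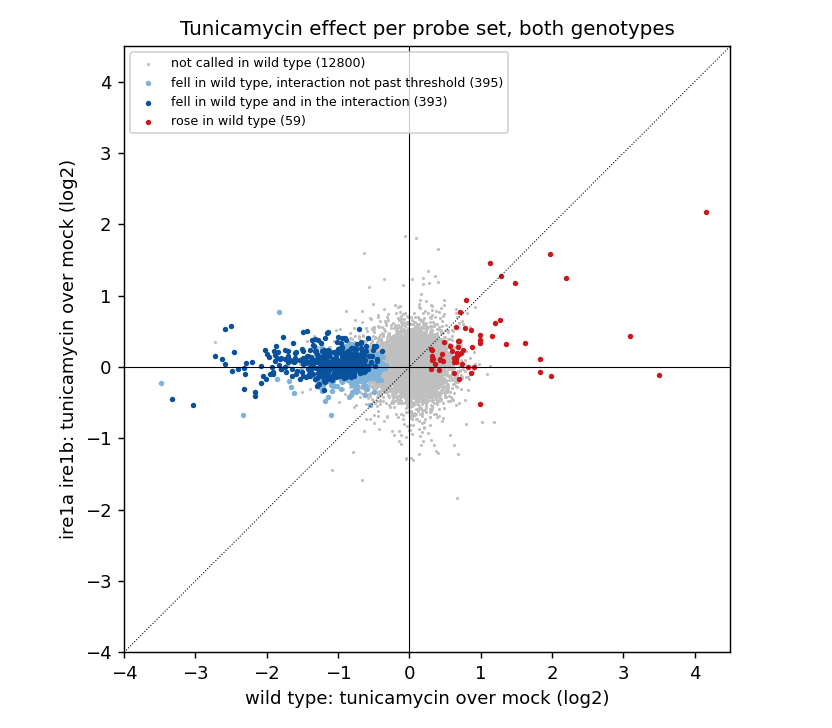
Each point is 1 of 13647 tested probe sets, with its log2 change after tunicamycin in wild type on the x axis and in ire1a ire1b on the y axis; the dotted line marks equal changes. The 788 falls in wild type (blue, the 393 that also passed in the interaction in dark blue) lie around 0 on the y axis, with a median of +0.02, while 49 of the 59 rises (red) lie above 0.

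The same comparison in ire1a ire1b asks what tunicamycin changed without IRE1. In the mutant, 6 probe sets rose, each by more than 2-fold, and 0 fell in limma's test (319 rose and 182 fell at an unadjusted p below 0.05). The named rises were AT4G34630 (+1.58 ± 0.18, adjusted p = 0.0026), AT4G29520 (+1.27 ± 0.19, adjusted p = 0.028) and AT4G35985 (+1.25 ± 0.18, adjusted p = 0.023). Each same-numbered pair of mock and tunicamycin arrays of the mutant correlated above 0.1, the criterion used here for pairing, and with replicate as a block 11 probe sets rose and 0 fell. With only the mutant's own 6 arrays in the fit 1 rose, and AT4G34630, AT4G29520 and AT4G35985 had adjusted p values of 0.19, 0.63 and 0.25; 3 rose without ire1a ire1b tunicamycin array 1, with the same number without ire1a ire1b mock array 2 or 3 or wild-type tunicamycin array 2. Without ire1a ire1b tunicamycin array 1 AT4G29520 had an adjusted p of 0.16, and without ire1a ire1b mock array 3 AT4G35985 had 0.12.

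Of the 6 probe sets, 4 also rose in wild type: AT4G34630, AT4G29520 and a pair with no gene listed. AT4G35985 had +0.18 ± 0.18 in wild type, and its interaction was -1.06 (adjusted p = 0.037). Next in the mutant, short of the threshold, were AT3G14780 (+1.83 ± 0.30, adjusted p = 0.061), the calnexin gene AT5G07340 (+0.77 ± 0.14, adjusted p = 0.12) and the glutathione transferase gene GSTU22 (+0.87 ± 0.16, adjusted p = 0.17). With replicate as a block AT3G14780 and GSTU22 rose, with adjusted p values of 0.031 and 0.039. The largest falls by p, AT5G07580 (-0.97 ± 0.21, adjusted p = 0.31) and AT3G13760 (-0.95 ± 0.23, adjusted p = 0.40), did not pass, and the latter's signal under tunicamycin (52.0) lay below the filter value. As a group, the 7 UPR genes had a median of +0.52 (camera adjusted p = 3.61e-09, and 0.0092 with an estimated correlation); 0 passed over all probe sets and 5 rose adjusted over the list alone, the same number as at an unadjusted p below 0.05. Of the 72 secretory cargo genes, 0 passed either over all probe sets or adjusted over the list alone (7 rose and 0 fell at an unadjusted p below 0.05), and their median was +0.04 (camera adjusted p = 0.45). Of 35 peroxidase genes 0 passed in limma (5 rose at an unadjusted p below 0.05), and 2 rose adjusted over the list alone.

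**Figure D2:**
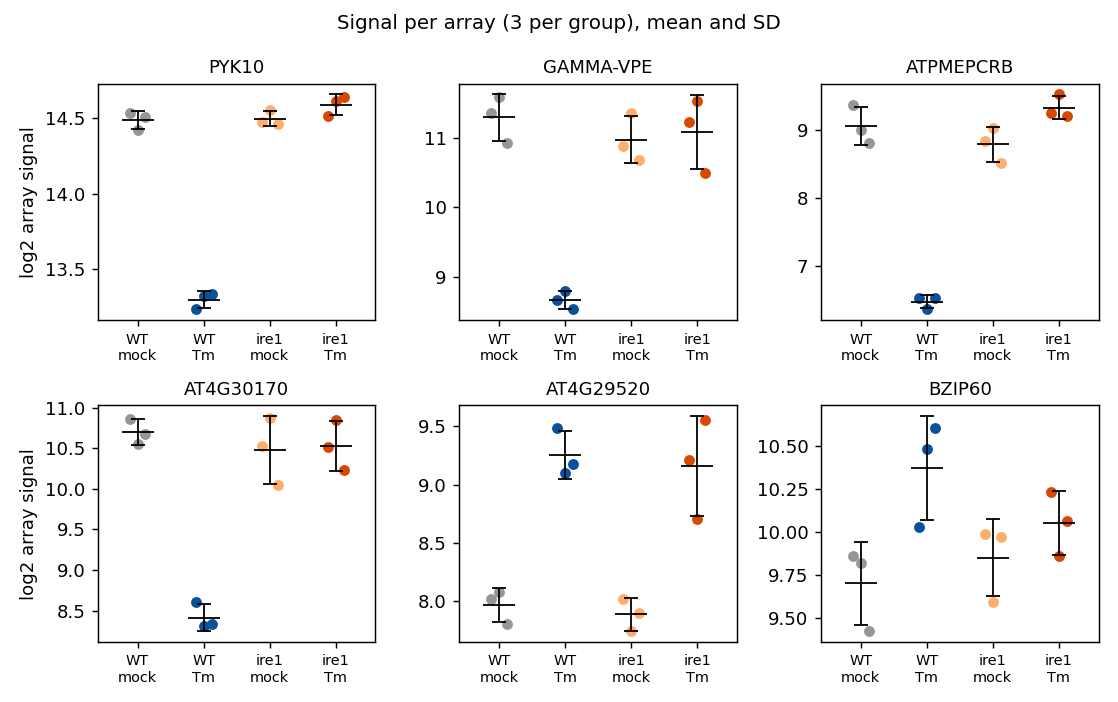
Log2 array signal of 6 genes on each of the 12 arrays (points), with the mean and SD of each group of 3 (bars); WT is wild type, ire1 is ire1a ire1b and Tm is tunicamycin. For PYK10, GAMMA-VPE, ATPMEPCRB and the peroxidase AT4G30170 the 3 wild-type tunicamycin arrays lie below all others, and for AT4G29520 the tunicamycin arrays of both genotypes lie above all mock arrays.

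The interaction tests whether the response to tunicamycin differed between the genotypes, which is the question of IRE1-dependent loss. ATPMEPCRB fell 5.99-fold in wild type and had +0.54 ± 0.17 in the mutant, an interaction of -3.12 ± 0.24 (adjusted p = 1.30e-05). GAMMA-VPE (-2.74 ± 0.34), AT4G29270 (-2.37 ± 0.20), the peroxidase AT4G30170 (-2.34 ± 0.28) and ChiC (-2.31 ± 0.41) also passed, as did AT3G56060 (-2.67 ± 0.51), whose wild-type tunicamycin signal of 48.2 leaves the size uncertain. PYK10 had an interaction of -1.28 ± 0.10, NAI2 of -1.56 ± 0.15 and COB of -0.98 ± 0.16. AT1G33600, likewise of uncertain size, had -3.26 ± 0.85 and did not pass (adjusted p = 0.059).

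In the interaction 406 probe sets were lower and 12 higher in wild type, by limma with Benjamini-Hochberg adjustment. Of the 788 falls in wild type, 393 (49.9%) also passed downward in the interaction, 181 of them of 1 named gene and 219 with a wild-type fall of 2-fold or more. Independent lists of these sizes would share 23.4, but both tests use the wild-type arrays. In 20 simulations with the called wild-type effects in both genotypes and no interaction, chosen after the data were seen, a median of 700 fell in wild type and at most 0 of them passed in the interaction. With no interaction simulated, the adjustment leaves few such calls by design, so this says little about the 393. In the mutant the 788 falls had a median change of +0.02 (95% interval 0.01 to 0.04), with 338 below 0 and 450 above it; 0 passed the threshold in limma, and 13 fell and 16 rose at an unadjusted p below 0.05. The interaction count was 635 without ire1a ire1b tunicamycin array 3, and 940 with array weights. The 12 higher became 6 without wild-type tunicamycin array 2 or mock array 3, and 7 without wild-type mock array 1, wild-type tunicamycin array 3 or ire1a ire1b tunicamycin array 2. They became 29 without ire1a ire1b tunicamycin array 3, 5 with a filter at the 60th percentile and 87 with array weights.

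By list, 21 of the 72 secretory cargo genes passed downward in the interaction and 0 upward (0 also at an unadjusted p below 0.05), 36 downward adjusted over the list alone, with a median of -0.67 (camera adjusted p = 5.99e-28, and 0.00078 with an estimated correlation). They included 11 of 35 peroxidases (22 adjusted over the list alone; adjusted p = 0.0017 with an estimated correlation) and 6 of 7 vacuolar and ER body genes (6 adjusted over the list alone; adjusted p = 0.0092 with an estimated correlation). They also included 1 of 15 XTH and expansin genes, EXGT-A3 at -1.05 ± 0.17, with 4 adjusted over the list alone and an adjusted p of 0.014 with an estimated correlation. Of 8 secreted defence genes 1 passed, OSM34, likewise adjusted over the list alone; the list's call was lost with an estimated correlation (adjusted p = 0.055), without ire1a ire1b tunicamycin array 3 (0.065) and without ire1a ire1b mock array 2 (0.055). In the UPR list ATERDJ3B, an ER co-chaperone gene, passed downward (-0.73 ± 0.16, adjusted p = 0.020), with -0.18 ± 0.11 in wild type and +0.55 ± 0.11 in the mutant, and it alone passed adjusted over the list alone. As a group the UPR genes had an interaction median of -0.06 (camera adjusted p = 0.29, and 0.63 with an estimated correlation). The list was therefore not called different between the genotypes. The 66 plastid-encoded genes had a median of +0.14; 0 passed (2 rose at an unadjusted p below 0.05), and the list's call was lost with an estimated correlation (adjusted p = 0.63). Across tested probe sets the effects in the 2 genotypes had a Pearson r of 0.01 and a Spearman rho of -0.004, a description across genes, which are not independent replicates.

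Gene titles, taken from synonyms, gave the same contrast on a small base. They are not independent of the lists, as PRXR1, for example, counts in both. Among 656 tested genes with a title, 49 (7.47%) had a word of secreted proteins in it. Of the titled genes, 49 fell in wild type, and 17 of these (34.7%) had such a word, an odds ratio of 9.48 (95% interval 4.45 to 19.8, Fisher's exact test, two-sided p = 4.93e-09). Of the 28 that were lower in an IRE1-dependent way, 11 (39.3%) did, an odds ratio of 9.97 (3.93 to 24.5, Fisher's exact test, two-sided p = 1.08e-06). Most tested genes carry no title here. Fisher's test also takes genes as independent, while genes that vary together are not, so its p-values may be too small. It takes no account of signal either, though few dim probe sets fell.

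**Figure D3:**
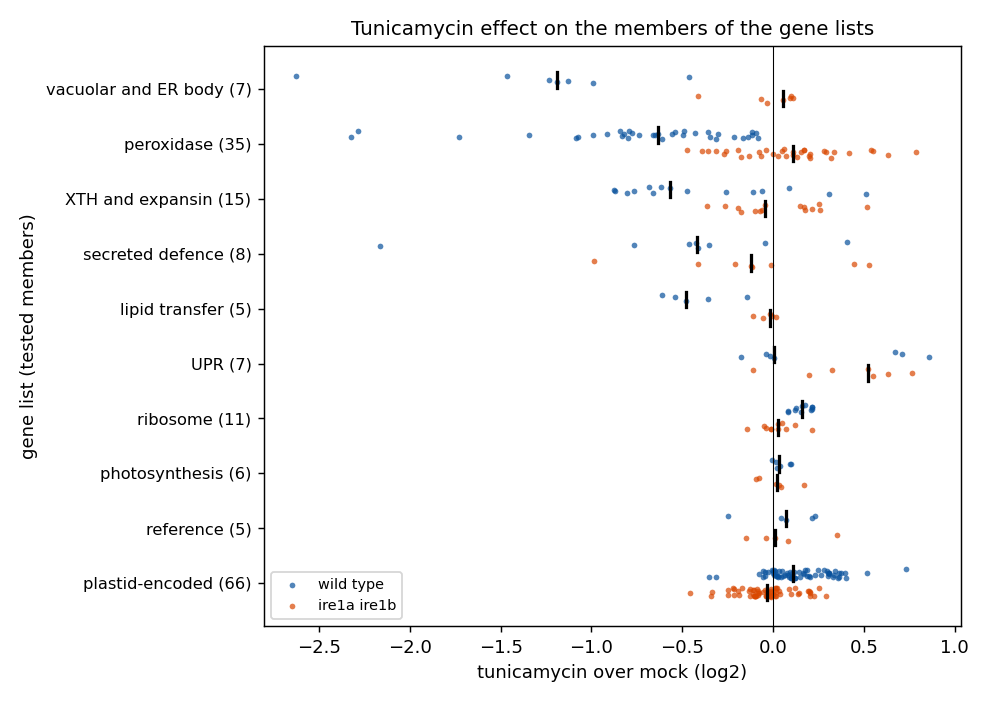
Log2 change after tunicamycin of each tested member of 10 gene lists in wild type (blue) and ire1a ire1b (orange), with the median as a black bar and the number of members in brackets. In wild type the medians run from -1.19 for vacuolar and ER body genes to +0.16 for ribosomal protein genes, and in the mutant the UPR list stands apart at +0.52.

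The genotypes were compared under mock to see how the mutant differed before ER stress. AT5G09480, AT5G59330 and AT4G38080 were lower in ire1a ire1b, with log2 differences of -1.86 ± 0.26, -1.78 ± 0.25 and -1.65 ± 0.25. AT2G27140, of the small heat shock family, was 4.33-fold higher (from 92.3 ± 23.2 to 390.2 ± 8.97). AT3G27150, a kelch-repeat F-box gene, was lower (from 398.9 ± 74.1 to 54.4 ± 22.3) and the reticulon-like gene AT3G18260 higher (from 33.5 to 165.4), each with 1 signal below the filter value of 68.7, so the sizes are uncertain. AT1G68230 (+1.92 ± 0.24), the glutathione transferase gene GSTF4 (+1.74 ± 0.22) and AT1G29520 (+1.67 ± 0.18) were also higher. In all, 22 probe sets were higher and 44 lower, so that 66.7% were lower, against 51.1% (24 of 47) with each array centred on its median. The majority turned without wild-type mock array 1, 2 or 3, where 48.5%, 46.9% and 47.1% of the calls were lower. The count was 32 without wild-type mock array 2, 33 without wild-type mock array 1, 34 without wild-type mock array 3 or ire1a ire1b mock array 1, and 103 without ire1a ire1b tunicamycin array 3 (33 higher and 70 lower). The 44 lower also became 19 without ire1a ire1b mock array 1, 27 without wild-type tunicamycin array 2, and 28 without wild-type tunicamycin array 1 or ire1a ire1b mock array 3.

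Of the 72 secretory cargo genes 1 was lower under mock, the peroxidase gene AT3G01190 (-0.73 ± 0.14, adjusted p = 0.042), with 6 higher and 7 lower adjusted over the list alone, and the median was -0.04. The 393 transcripts with an IRE1-dependent fall had a median genotype difference of -0.08 under mock, and 4 of them were lower and 1 higher past the threshold. The 8 secreted defence genes had a median of +0.59 (camera adjusted p = 0.00011, and 0.014 with an estimated correlation); 0 passed over all probe sets, 2 adjusted over the list alone and 3 at an unadjusted p below 0.05, led by PDF2.1 (+1.46 ± 0.38) and AT2G43590 (+1.07 ± 0.33). The calls of the ribosome list (median +0.10) and the plastid-encoded list (+0.15) were lost with an estimated correlation (adjusted p = 0.63 and 0.17).

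Under tunicamycin the mutant was compared with wild type directly. ATPMEPCRB was 7.21-fold higher in ire1a ire1b, GAMMA-VPE 5.35-fold and the peroxidase AT5G64120 5.44-fold, while AT1G33600 (+3.21 ± 0.60), AT3G20450 (+2.65 ± 0.64) and AT2G16005 (+2.57 ± 0.50) were also higher. Lower in the mutant were AT4G39675 (-3.14 ± 0.81), AT3G27150 (-2.94 ± 0.32), AT5G10040 (-2.76 ± 0.60), AT5G26200 (-2.71 ± 0.63), AT2G17850 (-2.17 ± 0.46) and AT1G33055 (-2.12 ± 0.54). The sizes for AT1G33600, AT3G20450, AT3G27150 and AT5G26200 are uncertain, as the lower signal of each (67.2, 57.1, 53.9 and 37.8) lay below the filter value. In limma with Benjamini-Hochberg adjustment 911 probe sets were higher and 413 lower, 348 and 104 of them by 2-fold or more. Of the 22 higher and 44 lower under mock, 21 and 23 passed the same way under tunicamycin, on other arrays, against 1.47 and 1.33 from independent lists. The lists are not independent, however. Both comparisons share the filter and the estimate of spread, and the mutant's mock and tunicamycin arrays met the criterion for pairing. The count was 875 without wild-type tunicamycin array 2 and 877 without ire1a ire1b tunicamycin array 2. The 413 lower became 187, 208 and 232 without wild-type tunicamycin array 3, 2 and 1, 221 without ire1a ire1b tunicamycin array 2 and 264 with only the 6 arrays compared. Without ire1a ire1b tunicamycin array 2 the AT3G20450 call ended (adjusted p = 0.064), and without wild-type tunicamycin array 3 those of AT4G39675, AT5G26200 and AT1G33055 (0.10, 0.068 and 0.10).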

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

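The results here are those where the response to tunicamycin differed between the genotypes by the interaction test, and the other splits of the samples; the tests on the split of 904 calls were chosen after that result was seen, those on the fall in wild type before.

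The effect of tunicamycin differed between the genotypes for 406 probe sets with a lower and 12 with a higher tunicamycin effect in wild type than in ire1a ire1b. Gene lists that differed the same way were the secretory cargo (median -0.67), peroxidases (-0.73), vacuolar and ER body genes (-1.18), XTH and expansin genes (-0.40), secreted defence genes (-0.38) and, upward, plastid-encoded genes (+0.14). The calls of secreted defence and plastid-encoded genes were lost with an estimated correlation (adjusted p = 0.055 and 0.63). Among named genes the differences were -3.12 for ATPMEPCRB, -2.74 for GAMMA-VPE, -2.37 for AT4G29270, -2.34 for AT4G30170 and -2.31 for ChiC. They were -2.28 for AT1G21670, -2.18 for AT1G21680, -2.05 for the lipase-like gene AT1G33811, -2.01 for AT5G19890, -1.98 for the aspartyl protease gene AT1G62290 and -1.98 for the subtilase gene AT3G14067. Upward they were +2.11 for AT3G55700, +1.51 for AT1G10980 and +1.73 for AT5G49100. The sizes of these 3, and of -2.67 for AT3G56060, are uncertain, since at least 1 group signal of each lay below the filter value of 68.7. Leaving out 1 array ended the calls of AT5G49100 and AT5G19890 in 9 of 12 fits each (adjusted p up to 0.11 without wild-type tunicamycin array 3 and 0.13 without wild-type mock array 2). It ended that of AT1G21670 in 7 (up to 0.086 without wild-type tunicamycin array 1), that of AT1G62290 in 4 and that of AT1G21680 in 1 (0.052 each, without ire1a ire1b tunicamycin array 2 and wild-type mock array 2).

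The fall of 788 probe sets in wild type was weighed against 3 technical causes. Array scaling was to lose most falls under another centring, but with every array centred on its median 766 fell. That centring moved the median change of all tested probe sets only from +0.09 to +0.11, so it could hardly have removed the falls. Both scalings set changes relative to the bulk of the array, so an even shift of most transcripts stays unseen. Degraded RNA was to lower secretory cargo and the ribosome, proteasome and photosynthesis genes alike. Their medians differed by -0.72 (95% interval over genes -0.86 to -0.59). The common scaling of the arrays would hide an even loss whatever this difference is, so the test does not decide on even loss. A loss that differs between transcripts stays open, since this difference does not bear on it. The 3' over 5' ratios differed by 0.08 in wild type. There the arrays ran from 1.23 to 1.29 under mock and from 1.20 to 1.48 under tunicamycin (log2). The largest range within any group, 0.43, was in the ire1a ire1b tunicamycin arrays. With these ratios as a covariate, chosen after the data were seen, 920 fell, among them 781 of the 788. The 788 then had a median of -0.89, against -0.85 without the covariate, so the falls did not shrink. But 0 probe sets followed the ratio in limma (2100 at an unadjusted p below 0.05), so this fit does not decide on uneven loss. Less root tissue in those samples stays open too: the photosynthesis list lay -0.0536 from the median of all tested probe sets, but no root marker has a named probe set here, and peroxidase and PYK10 transcripts are abundant in roots. Decay through IRE1, the biological candidate that the design names, would give the interaction seen. It cannot be called established while uneven loss of RNA and tissue share are open. Whether actinomycin D blocked transcription fully was not tested either, and 59 probe sets rose in wild type.

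Other splits of the samples bear on whether these counts could arise from any grouping. For the interaction, genotype labels were permuted within each treatment in 100 splits: 3 gave 418 calls or more, the real one included, and the highest other gave 589; for the IRE1-dependent falls 1 of 100, the real one, gave 393, and the highest other 331. These shares exclude chance only if the arrays can be exchanged freely, while the mutant's mock and tunicamycin arrays met the criterion for pairing. With same-numbered arrays moved together, chosen after the data were seen, there are 10 splits, too few for a share under 0.05 (real 418, highest other 0, and 393 against 0). The count also hardly rests on the mock labels: the 6 splits that kept the tunicamycin labels gave 268 to 589 calls, and splits that neither kept nor exchanged them whole at most 1. For 3 arrays against 3 there are likewise 10 splits, too few for a share under 0.05. There the real splits gave 847 calls in wild type (1 of 10 splits as many, highest other 0), 66 between genotypes under mock (1, highest other 0) and 1324 under tunicamycin (1, highest other 0). For tunicamycin in ire1a ire1b 2 of 10 splits gave 6 or more, and the highest other gave 904.

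That split of 904 calls points to a structure among the ire1a ire1b arrays: it parts mock 1, mock 3 and tunicamycin 3 from mock 2, tunicamycin 1 and tunicamycin 2. It parts 1 of the 3 numbered pairs, and among the 4 splits that part all pairs the highest other than the real one gave 0. Swapped labels of mock array 2 and tunicamycin array 3 would leave the transcripts that rose in wild type lower on the latter. They were higher there, by a median of 0.30 (95% interval over transcripts 0.18 to 0.47). This sets 1 array against 1 from opposite sides of the split. The interval resamples transcripts, not arrays, so it does not exclude swapped labels. Batches marked by the replicate number may contribute, since the pairs of numbers 2 and 3 had correlations of 0.44 and 0.51, but the lowest same-numbered pair lay -0.0448 from the highest differently numbered one, so this cause cannot be told apart from chance with 3 pairs; no biological explanation was tested.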

How the results depend on the processing

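Of the named genes and lists that were called, none changed sign under an alternative, but the majority of calls between genotypes under mock turned from lower to higher without wild-type mock array 1 (17 higher, 16 lower), 2 (17 and 15) or 3 (18 and 16). Array weights moved 4 counts by more than 1.5 times: 13 for tunicamycin in ire1a ire1b, 940 for the interaction, 907 between genotypes under mock and 771 for IRE1-dependent falls; they gave ire1a ire1b mock array 1 a weight of 5.79. With replicate as a block, shared by both genotypes, the counts were 11 in ire1a ire1b, 105 between genotypes under mock, 622 in the interaction, 1067 in wild type and 1729 between genotypes under tunicamycin. A block for the mutant's arrays alone was not fitted. In ire1a ire1b, where the criterion for pairing was met, the shared block brought AT3G14780 and GSTU22 past the threshold (adjusted p = 0.031 and 0.039) and changed no other named call. Elsewhere the numbers were not taken to pair arrays (correlations between genotypes 0.08, 0.34 and 0.39 under mock, and -0.10, -0.005 and 0.03 under tunicamycin); as a hint from the data, 6 of 6 mock arrays of the genotypes correlated best with their own number, but 1 of 6 tunicamycin arrays and 4 of 6 wild-type arrays. With only the 6 arrays compared they were 1 in ire1a ire1b and 42 between genotypes under mock. For array weights, block and 6 arrays the cause was not tested. Leaving out 1 array gave 593 to 980 calls in wild type, 3 to 8 in ire1a ire1b, 285 to 635 in the interaction, 32 to 103 between genotypes under mock, 875 to 1451 under tunicamycin and 273 to 581 IRE1-dependent falls. The highest interaction, mock, tunicamycin and IRE1-dependent counts all came without ire1a ire1b tunicamycin array 3. The secretory cargo medians ran from -0.65 to -0.57 in wild type and from -0.78 to -0.59 in the interaction. Quantile normalization, centring, both filters, the pseudocount and eBayes without a trend kept each of these counts within 1.5 times. Over the alternatives, the named genes kept their side of the threshold in 2900 cases, lost a call in 201 and gained it in 27; the lists did so in 831, 21 and 26. The hydropathy settings of 2.0 and 2.5 were not run, as no protein sequence was used here. Signals near the filter of 68.7 limit small falls: falls are seen less among dim probe sets, and 3 arrays per group recovered 44% of simulated interactions of log2 1.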

Other observations

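The hypotheses on the rises and the low-oxygen genes were formed after the results were seen, as were the lists they use; the tests of array scaling and of a deviating array for the low-oxygen genes were set before their values were computed.

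Families grouped by gene symbol, chosen after the data were examined (51 tests adjusted together), added further secretory enzymes to the fall in wild type. Of 15 serine carboxypeptidase-like (SCPL) genes 8 fell, with a median of -0.72 in wild type and -0.03 in ire1a ire1b (adjusted p = 0.0051 in wild type with an estimated correlation), and of 9 beta-glucosidase (BGLU) genes 5 fell, with a median of -0.58 against +0.14 (0.0086). Of 6 SWEET sugar transporter genes, which encode membrane proteins, 3 fell (SWEET11, SWEET16 and SWEET17; median -0.64, adjusted p = 0.11 with an estimated correlation). Of 6 RALFL peptide hormone genes 2 fell, RALFL31 and RALFL33 (0.082). The lists of 11 CYP, 13 TBL and 8 TET genes also passed with the preset correlation, with medians of -0.56, -0.29 and -0.22 and 2, 2 and 1 falls, and were lost with an estimated correlation (adjusted p = 0.11, 0.15 and 0.11). The 7 EXPA and 5 XTH genes, part of a list fixed in advance, had -0.23 and -0.57 and did not pass (adjusted p = 0.058 and 0.15). The medians of 23 UGT, 9 GSTU, 11 UBP, 9 VPS, 8 ATG, 6 SEC and 5 PUB genes were between +0.06 (UBP) and +0.21 (VPS) in wild type, and their adjusted p values with an estimated correlation were 0.58 or more.

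Of the 59 rises in wild type 4 also passed in ire1a ire1b. The 59 had a median of +0.73 in wild type and of +0.22 in ire1a ire1b (95% interval 0.12 to 0.33), where 49 of 59 were above 0. Relative to all tested probe sets the median in the mutant was 0.21 (0.10 to 0.31), but the mutant arrays entered the filter and the estimate of spread that chose them. With the filter and fit on the 6 wild-type arrays alone, chosen after the data were seen, 116 rose, and their median in the mutant, again relative to all tested, was 0.09 (0.05 to 0.15), with 87 of 116 above the median of all tested. The intervals resample transcripts, not arrays, so they hold no spread between arrays. A response shared by both genotypes may underlie part of the rises, though a small one. Whether it is escape from actinomycin D or slower decay was not tested. Of the 12 higher interactions 8 were rises in wild type, but that count ran from 6 to 29 with 1 array left out and was 87 with array weights. The interaction of AT3G55700 passed in each of the 12 fits without 1 array; it had +1.98 ± 0.24 in wild type, of uncertain size at a mock signal of 60.6, and -0.12 ± 0.24 in ire1a ire1b.

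Several transcripts lower in ire1a ire1b than in wild type under tunicamycin (AT4G39675, AT5G10040, AT2G17850, AT1G33055, AT4G33560, AT4G24110 and AT4G10270) belong to the known response to low oxygen, which led to a list of 46 such genes. Leaving out the 8 already named, 15 tested members had a median of -0.86 there, with 7 lower past the threshold, among them AT5G66985 (-1.52 ± 0.28), AT3G03270 (-1.42 ± 0.26) and AT4G27450 (-1.37 ± 0.27). The camera adjusted p was 7.31e-06, but 0.31 with an estimated correlation, since the members vary together (estimated correlation 0.47). A deviating array argues for a median that collapses without it. The smallest median with 1 ire1a ire1b tunicamycin array left out was -0.74. With 1 wild-type tunicamycin array left out, chosen after the data were seen, it was -0.73. With every array centred on its median it was -0.85. That centring moved the median of all tested probe sets only from -0.08 to -0.07, so it tests array scaling weakly. Without wild-type tunicamycin array 3, however, 4 members were lower past the threshold, and the calls of AT4G39675, AT1G33055 and AT4G10270 ended (adjusted p = 0.10, 0.10 and 0.096). Their median deviation was +0.66 on that array, against +0.20 and +0.23 on the others of its group, below 0 on 5 of 6 ire1a ire1b arrays, mock included, and +0.51 on ire1a ire1b mock array 2. A difference in oxygen supply or handling between the cultures of the genotypes, or a genotype effect, may account for it, and no test here tells these apart.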
